A study of Rattus norvegicus with 12 samples.

How the data were processed

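Total RNA of rat trigeminal ganglia was fragmented, part was kept as input and the rest was immunoprecipitated with an antibody to m6A, per the labels' protocols. Libraries were made with a low-input whole-RNA kit and sequenced on a NovaSeq instrument. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4 and the rat build Rnor_5.0, without their role or order. The peak names in the files begin with MACS, and no version of the caller is given in the sources used here. Peaks were called per sample, with 1 list for each of the 6 animal labels, and replicates were not pooled.

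Each row of the authors' lists is a peak assigned to an mRNA transcript and gene, with its chromosome, start and end. The peak numbering runs to 64607, 70530 and 68764 in NC-up rats 1, 2 and 3 and to 73269, 76826 and 70688 in ALKBH5-up rats 1, 2 and 3. The lists hold 39.6% to 43.2% of the highest peak number. The deposited fold enrichment is a ratio, as the peak caller gave it. The deposited score is 10 times the negative log10 of the caller's p-value, per the file headers, and its lowest value is 20 in every list, which is a p of 0.01. The deposited false discovery rate is in percent, per the file headers. At a false discovery rate of 5% the lists would hold 9, 1491 and 20 peaks in NC-up rats 1, 2 and 3 and 3386, 1561 and 51 in ALKBH5-up rats 1, 2 and 3, so it was not used as a filter. The fold, score and false discovery rate are the authors' values and served to describe, rank or filter peaks within a list. Across lists, 1 common fold minimum of 11.03, the median pooled over the NC-up lists, was an alternative for the counts, and the lists' medians of fold and score were set side by side without a test. All peaks lay on the 20 autosomes and X. Positions are of Rnor_5.0 as the files give them, with the start turned to 1-based counting. The transcript part of a peak and its sequence were not used here.

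A peak was a distinct chromosome, start and end. Peaks of the 6 lists were merged into regions where they overlapped by at least 1 bp, and a region was present in a rat if a peak of that rat was in it. Numbers of peaks and of genes per rat were compared by two-sided exact permutation over the 20 assignments of 6 rats, for which the smallest p is 0.1. Overlap was the share of a list's peaks met by a peak of another list, averaged over both directions, and was tested over the 10 splits of the rats into 3 and 3. Regions called in all 3 rats of a group and in none of the other were counted per direction and compared with the other splits. Groups were those of the labels.

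The 12 gene lists held 349 entries, of which 348 had a known symbol and 294 had a peak in at least 1 rat. Symbols were matched exactly or through a RefSeq gene table of the GRCr8 assembly, used for names alone, whose gene numbers matched 94.0% of the gene rows. Each list was tested by the number of members with a peak per rat (exact permutation). Its members with a lost or gained region were set against all other genes with a peak (Fisher's exact test). Adjustment was by Benjamini-Hochberg, over the 12 lists or the 24 tests. Genes named were Alkbh5 and Htr3a. In each direction, the 12 genes with the highest mean fold percentile among group-specific regions were added, leaving out symbols that begin with LOC or RGD or are no symbol. From each list came up to 4 members that differed most in rats with a peak and up to 2 with a peak in all 6 and the highest percentile. The 6 highest genes called in all 6 rats completed the rule. Some genes that the rule or a count takes in are not reported here.

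The counting of group-specific regions was tested on simulated data, with 200 lost and 200 gained regions placed among 41597. It found 78.5% of the lost and 80.5% of the gained regions, where the simulated calling rates allow 80.7%. The simulated groups gave 621 such regions and the highest other split 368. Outside the placed regions all simulated rats had the same calling rates. The simulation therefore checked the counting alone and could not show the effect of unequal list lengths or fold scales.

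The choices fixed before the data were examined are the tests, lists and naming rule above. The alternatives fixed then were a reciprocal overlap of 50%, presence per gene, stricter folds or p-values, equal list lengths, presence in 2 of 3 rats, each rat left out, and the replicate number as a block. Tests of read counts or normalized values per peak, and of position and sequence motif, had been planned in case the lists held such values, and were not run. No input or immunoprecipitated read number was used here, so no confidence interval or detection limit is given for a peak. Peaks with a score of at least 50 (a p of 1e-05 or smaller), exon shifts, the gene count with equal lists and a second background for the lists were added after seeing the data. The analysis used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.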

Results

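N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA, was mapped in the trigeminal ganglion, which holds the cell bodies of the sensory neurons of the face, of male Sprague-Dawley rats. The ganglion had been injected with a control vector (NC-up, n = 3) or with a vector for ALKBH5 (ALKBH5-up, n = 3), an enzyme that removes m6A from RNA. Each of the 6 samples gave 2 libraries, RNA pulled down with an antibody to m6A and the input RNA, so that 12 libraries led to 6 peak lists. The labels do not say whether a sample was 1 rat or a pool. It is called a rat below. Permutation and sign-flip p-values measure the spread between these samples. Fisher's exact tests of gene sets and pathways count genes, so their p-values do not measure that spread. The lists held 27902, 29285 and 28100 peaks in the NC-up rats and 29917, 30807 and 28020 in the ALKBH5-up rats, all assigned to mRNA transcripts. Read numbers were not analysed here, so the depth behind each peak is unknown. The study's title concerns ALKBH5 and the m6A of the mRNA of 5-HT3A, a serotonin-gated ion channel encoded by Htr3a.

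The first question was whether the mRNAs of the injected gene and of Htr3a carried peaks. Alkbh5 (NM_001191643) had a peak in all 6 rats, on chromosome 10 from 46679920 to 46680692. The authors' fold enrichment of this peak was 21.9 ± 7.92 (SD, n = 3) in the NC-up lists and 11.4 ± 2.02 (SD, n = 3) in the ALKBH5-up lists. The level of Alkbh5 RNA or protein was not analysed here, so its rise after injection was not checked. The median fold of all peaks was lower in every ALKBH5-up list than in every NC-up list, and within its own list the peak held a mean fold percentile of 83.4 ± 11.3 (SD, n = 3) in the NC-up and 82.1 ± 7.59 (SD, n = 3) in the ALKBH5-up rats. Another Alkbh5 region, from 46699983 to 46700552, was called in 2 NC-up rats and 1 ALKBH5-up rat. A further one, from 46689541 to 46689621, was called in 1 rat of each group. Htr3a (NM_024394) had 1 region, on chromosome 8 from 51803897 to 51804636. It was called in NC-up rats 1 and 3, in neither NC-up rat 2 nor any ALKBH5-up rat, and Fisher's exact test of 2 of 3 against 0 of 3 gave a two-sided p of 0.4. The peak caller's score, 10 times the negative log10 of its p, was 21.95 and 24.15, close to 20, the lowest score in every list. Its fold of 6.9 in NC-up rat 1 and 4.59 in NC-up rat 3 placed it at a mean percentile of 3.1, and its false discovery rate was given as 100% in both lists. That rate was high for most peaks there, with medians of 59.2% in NC-up rat 1 and 56.0% in NC-up rat 3.

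The number of m6A peaks was compared because ALKBH5 removes m6A, although a count of called peaks also depends on the depth, which was not analysed here. The ALKBH5-up lists held 29581 ± 1424 peaks (SD, n = 3) and the NC-up lists 28429 ± 748 (SD, n = 3). The difference of 1152 peaks was smaller than the spread in the ALKBH5-up group (two-sided exact permutation p = 0.3, n = 3 per group, where the smallest possible p is 0.1). Genes with at least 1 peak numbered 11491 ± 218 (SD, n = 3) in the ALKBH5-up rats and 11167 ± 134 (SD, n = 3) in the NC-up rats (exact permutation p = 0.2, n = 3 per group).

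**Figure D1:**
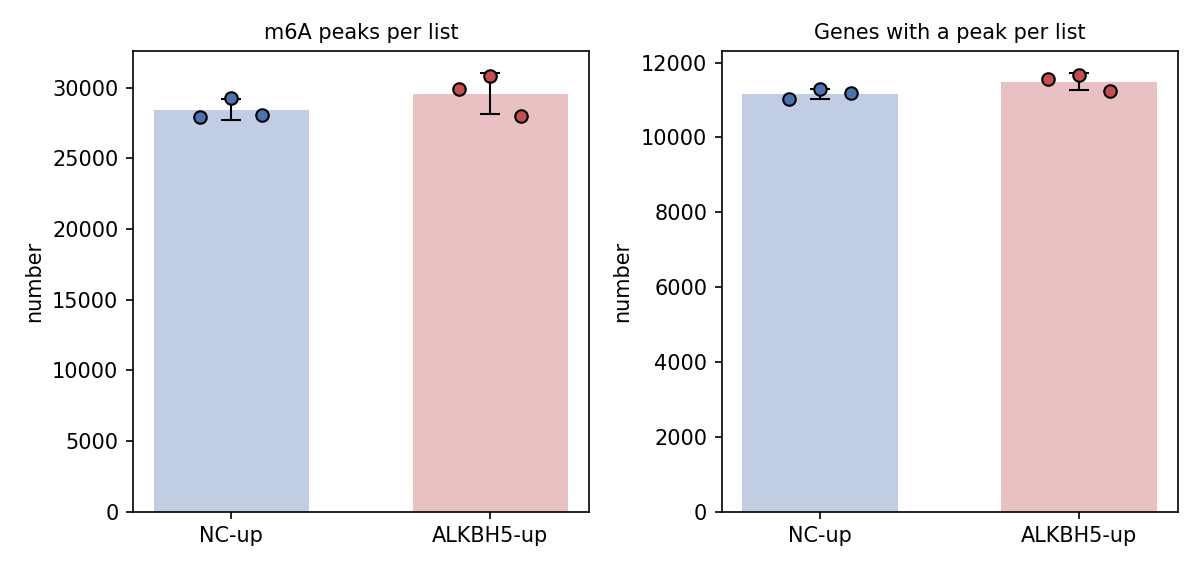
Number of m6A peaks (left axis panel) and of genes with at least 1 peak (right axis panel) per list in the NC-up and ALKBH5-up groups. Points are rats, bars are group means and error bars are SD (n = 3). The lowest ALKBH5-up list, with 28020 peaks, lies within the NC-up range of 27902 to 29285.

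Of 41597 merged regions, 18785 (45.2%) were called in all 6 rats, and of 13112 genes with a peak, 9541 (72.8%) had one in all 6. Among the latter, the 6 genes highest by mean fold percentile over all 6 lists were Zfp653 and Zfp217, zinc finger genes, Chd7, a chromatin remodeller, Nrg2, a neuregulin, Matk, a tyrosine kinase, and Ppm1a, a protein phosphatase. The Zfp653 region, on chromosome 8 from 23121360 to 23121840, had a fold of 88.8 ± 32.2 (SD, n = 3) in the NC-up lists and 51.7 ± 8.93 (SD, n = 3) in the ALKBH5-up lists. The Nrg2 region, on chromosome 18 from 28545374 to 28545890, had folds of 81.5 ± 20.3 and 41.5 ± 8.34 (SD, n = 3 each), on the lower fold scale of all ALKBH5-up lists. Rats of 1 group shared 82.9% of their peaks on average (6 pairs) and rats of different groups 82.4% (9 pairs). The difference of 0.557 percentage points was the largest of the 10 splits of the rats into 3 and 3 (exact permutation p = 0.1, the smallest possible, n = 3 per group), and the next split reached 0.494. It moved with single rats, a check chosen after seeing the data. It was 0.191 without ALKBH5-up rat 1 (exact permutation p = 0.9), 0.298 without NC-up rat 1 (exact p = 0.3), 0.362 without ALKBH5-up rat 2 (exact p = 0.5) and 1.15 without NC-up rat 2 (exact p = 0.1).

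Median fold was lower in every ALKBH5-up list than in every NC-up list. It was 14.8, 9.28 and 9.47 in NC-up rats 1, 2 and 3 and 6.12, 6.12 and 7.23 in ALKBH5-up rats 1, 2 and 3. At the 18785 regions called in all 6 rats, the medians were 17.9, 11.7 and 11.5 against 7.79, 7.84 and 8.76. The score at the same regions had medians of 149, 223 and 189 in the NC-up lists and 246, 268 and 214 in the ALKBH5-up lists. At 12341 of these regions (65.7%) the fold was lower in all 3 ALKBH5-up lists than in all 3 NC-up lists, and at 0 it was higher. By chance 5% would be so ordered in each direction, but the folds of a list move together, so the regions are not independent. The medians and these shares are given as a description, without a test.

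Regions called in all 3 NC-up rats and no ALKBH5-up rat numbered 139, in 138 genes, and were mostly weak. Their median fold percentile was 23.5 and their median score 37.3, against 62.9 and 218 for the regions called in all 6 rats, and 34 (24.5%) had a mean score of at least 50. Most of those genes kept other peaks: 105 of the 139 regions (75.5%) lay in genes with a peak in all 6 rats. The highest by fold percentile was in Rwdd1, on chromosome 20 from 29379699 to 29379902, with a fold of 22.6 ± 10.5 (SD, n = 3). A region in Cul4a, a scaffold of ubiquitin ligases, on chromosome 16 from 81228115 to 81228184, had a fold of 19.9 ± 8.52 (SD, n = 3). One in Mrpl12, a mitochondrial ribosomal protein gene, on chromosome 10 from 109252085 to 109252271, had a fold of 19.4 ± 9.16 (SD, n = 3). One in Ttc13, on chromosome 19 from 68144032 to 68144116, had a fold of 18.5 ± 4.20 (SD, n = 3). The other genes named by the rule were Mr1, which presents antigen to T cells, with a fold of 15.5 ± 1.35 (SD, n = 3), the axonemal dynein gene DNAH17, the ubiquitin ligase gene Neurl1, Ppp1r13b, Arhgef10, Cramp1l, the cytokine gene Il16 and the ganglioside activator gene Gm2a. At the gene level, 26 genes had a peak in all 3 NC-up rats and in no ALKBH5-up rat. They included RT1-A2, a class I histocompatibility gene whose reads can be shared with related genes of that family.

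Regions called in all 3 ALKBH5-up rats and no NC-up rat numbered 301, in 289 genes, and 81 genes had a peak in these 3 rats only. These regions were mostly weak too, with a median percentile of 20.8 and a median score of 42.9, and 101 (33.6%) had a mean score of at least 50. Of the 301 regions, 193 (64.1%) lay in genes with a peak in all 6 rats. Cfap157, a cilium gene, had a peak in all 3 ALKBH5-up rats only, on chromosome 3 from 17153922 to 17154193, with a fold of 11.9 ± 1.82 (SD, n = 3). Ucn2, which encodes the peptide urocortin 2, had one on chromosome 8 from 117079629 to 117080510, with a fold of 9.97 ± 5.71 (SD, n = 3). Gdnf, which encodes a survival factor for neurons, had one on chromosome 2 from 76919246 to 76919745, with a fold of 8.01 ± 4.22 (SD, n = 3). Aqp4, a water channel of glia, had a region on chromosome 18 from 6733645 to 6734059, with a fold of 8.09 ± 2.32 (SD, n = 3), while another Aqp4 region was called in 2 NC-up and 3 ALKBH5-up rats. Complexin 1 (Cplx1), a regulator of transmitter release, had 2 such regions, with folds of 7.20 ± 0.570 and 2.76 ± 0.288 (SD, n = 3). The latter lay at a mean fold percentile of 1.47. Emid1, Riok2, Micu3, the ribosomal protein gene Rpl39, Ccdc102a and Tmem100 completed the genes named by the rule, together with Ttc13. In Emid1 another region, called in 3 NC-up rats and 1 ALKBH5-up rat, lay less than 10 kb from the gained one. In Ttc13 the gained region, from 68141180 to 68141289 with a fold of 14.1 ± 1.52 (SD, n = 3), lay less than 10 kb from the lost one.

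The groups gave 440 such regions in both directions, and 1 of the other 9 splits of the 6 rats gave more, 455. In that other split, 345 regions were called only in NC-up rat 2 and ALKBH5-up rats 1 and 2, which had the longest lists. This exceeded the 301 regions called only in the ALKBH5-up rats. At the gene level the groups gave 107 and the highest other split 64. A single region cannot go below p = 0.1 in Fisher's exact test with 3 rats against 3, so no region was called on its own. Taking the same number of peaks from every list moved the counts to 191 and 228, that is from 2.17 to 1.19 regions gained per region lost. Leaving out NC-up rat 1 gave a ratio of 1.28 (400 and 514 regions), and leaving out ALKBH5-up rat 2 gave 1.39 (403 and 562 regions).

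**Figure D2:**
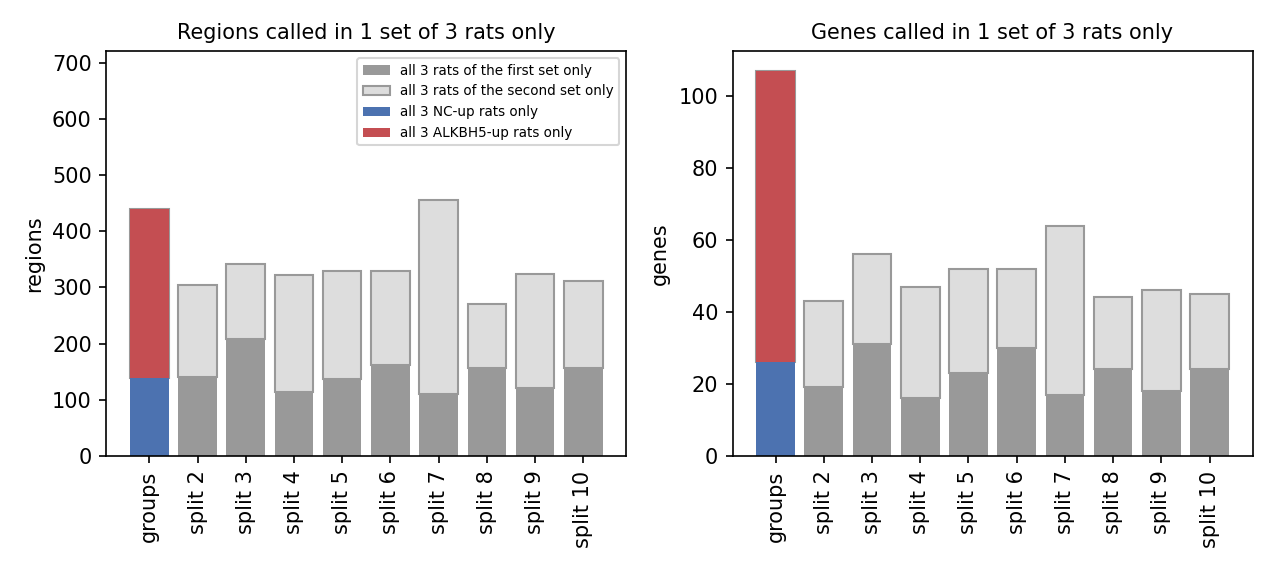
Regions (left) and genes (right) called in all rats of 1 set of 3 and in none of the other set, for the real groups and for the other 9 splits of the 6 rats. Bars are stacked counts. The real groups give 440 regions, with 455 in the highest other split, and 107 genes, with 64 in the highest other split.

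Genes of sensory neuron function were read from 12 lists fixed before the data were examined. Of 55 nociceptor and sensory ion channel genes, 45 had a peak in all 6 rats, with 48.0 ± 1.00 members (SD, n = 3) in the NC-up and 49 ± 1.73 (SD, n = 3) in the ALKBH5-up rats (exact permutation p = 0.7, n = 3 per group). Hcn2, a pacemaker channel, and Cacna1e, a calcium channel, had the highest fold percentiles, 99.7 and 99.1. Scn4b, a sodium channel subunit, had a peak in 1 NC-up and 3 ALKBH5-up rats, and Trpa1 and Asic3 in 2 and 3, while 1 other member had one in more NC-up rats. Of 20 serotonin receptor and transport genes, 8 had a peak in all 6 rats, Htr2a and Htr4 highest by fold percentile. The mean was 11.3 in both groups, with SDs of 0.577 and 2.08 (exact permutation p = 1, n = 3 each). In this list 3 members had a peak in more NC-up rats and 4 in more ALKBH5-up rats. Beside Htr3a, the former were Htr5a (3 NC-up and 2 ALKBH5-up rats, turned to 33.3 percentage points more ALKBH5-up rats at a score of at least 50) and the serotonin transporter gene Slc6a4 (1 and 0). The latter were Htr2b (0 and 1) and, named after their values were seen, Tph2 (0 and 1), Maoa (1 and 2) and Maob (2 and 3). Of 28 genes for GABA and glutamate receptors, 20 had a peak in all 6 rats and the mean was 22.7 ± 0.577 (SD, n = 3) in both groups (exact permutation p = 1). In this list 3 members had a peak in more ALKBH5-up rats and 3 in more NC-up rats. The former were Grin2a (1 NC-up and 3 ALKBH5-up rats) and, named after their values were seen, Gabrb1 and Grm5 (0 and 1 each), and the latter Gabrg3 (2 and 0), Gria1 (2 and 1) and Gabra3 (1 and 0). Of 33 synapse and axon guidance genes, 28 had a peak in all 6 rats, among them Epha4 and Rims1. The mean was 28.3 ± 0.577 members (SD, n = 3) in the NC-up and 29 ± 1.00 (SD, n = 3) in the ALKBH5-up rats (exact permutation p = 0.7), and the difference changed sign with folds above each list's median (-2 members). In that list 3 members, among them Syn1 and Slit3, named after their values were seen, had a region in the ALKBH5-up rats only (Fisher's exact test, adjusted p = 0.222).

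Of 32 neuropeptide, opioid and neurotrophin genes, 25.3 ± 1.15 (SD, n = 3) had one in the ALKBH5-up and 22.7 ± 0.577 (SD, n = 3) in the NC-up rats, with every ALKBH5-up rat above every NC-up rat (exact permutation p = 0.1, the smallest possible, n = 3 per group, adjusted p = 0.6 over the 12 lists). With folds above each list's median the difference was 1.67 members and the groups were no longer apart (exact permutation p = 0.4). The 5 members that differed all had more ALKBH5-up rats with all peaks of the lists, while with folds above each list's median Ramp1 turned to -33.3 percentage points of rats. They were Gdnf (0 and 3 rats), Calca, which encodes the pain peptide CGRP (1 and 3), Ramp1, a part of the CGRP receptor (1 and 2), Gal (0 and 1) and Calcb (0 and 1). Sstr2 and Bdnf had the highest fold percentiles among members with a peak in all 6 rats. In the same list 3 of 27 members had a region called in the NC-up rats only, 11.1% against 1.03% of the other genes. Fisher's exact test gave p = 0.00277, and p = 0.0666 after adjustment over 24 tests, the 12 lists in both directions. Named after their values were seen, Ret and Gfra2, receptors for ligands of the GDNF family, were among the 3. All 3 kept a peak elsewhere in all 6 rats. Leaving out any 1 of the other 5 rats gave 3 members and an adjusted p of 0.159 to 0.598 by the same exact test. Without ALKBH5-up rat 3, where all regions called in the NC-up rats only rose from 139 to 293, there were 5 members (exact test, adjusted p = 0.00667).

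Satellite glia and Schwann cell markers had a peak in 16.0 ± 1.00 of 25 genes (SD, n = 3) in the ALKBH5-up and 12.7 ± 0.577 (SD, n = 3) in the NC-up rats, again without overlap (exact permutation p = 0.1, the smallest possible, n = 3 per group, adjusted p = 0.6). With folds above each list's median the difference was 1 member (exact permutation p = 0.6). In all, 6 members had a peak in more ALKBH5-up rats and 2 in more NC-up rats. The myelin genes Pmp2 and Prx and the glial fatty acid binding protein gene Fabp7 had a peak in all 3 ALKBH5-up rats and in no NC-up rat. The folds of Pmp2, Prx and Fabp7 were 6.94 ± 0.441, 2.34 ± 0.290 and 4.58 ± 0.867 (SD, n = 3). Their mean fold percentiles were 55.1, 0.24 and 22.5, so Prx lay at the floor of the ALKBH5-up lists. The lowest fold of any peak of NC-up rat 1 was 3.7, so that list held no peak with a fold as low as that of Prx. Fa2h, an enzyme of myelin lipids, had a peak in 3 NC-up rats and 1 ALKBH5-up rat, and Kcnj10 and Gja1 in all 6 rats. These 3 gained members were 16.7% of the 18 with a peak, against 2.18% of the other genes (Fisher's exact test, p = 0.00677, adjusted p = 0.0812 over 24 tests). Leaving out any 1 of the rats other than ALKBH5-up rat 3 gave 3 to 4 members and an adjusted p of 0.0918 to 0.332 by the same exact test. Without ALKBH5-up rat 3, where all regions called in the ALKBH5-up rats only rose from 301 to 906, there were 5 members (exact test, adjusted p = 0.0498). Cytosolic ribosomal protein genes, chosen after the data were first examined, differed between the groups in the same direction. Of 59 with a peak in any rat, 36, 38 and 40 had one in the NC-up and 55, 54 and 43 in the ALKBH5-up rats (exact permutation p = 0.1, n = 3 per group). Sensory neuron markers numbered 22, 19 and 13 of 25 in the ALKBH5-up rats and 15, 15 and 14 in the NC-up rats (exact permutation p = 0.4, n = 3 per group). The difference of 3.33 members came to 0.333 with folds above each list's median (exact p = 1), 1.33 without ALKBH5-up rat 1 (exact p = 0.7) and 5.83 without ALKBH5-up rat 3 (exact p = 0.1). Of these markers 7 had a peak in more ALKBH5-up rats and 1 in more NC-up rats. Tubb3, Stmn2 and Spp1 had a peak in 0 NC-up and 2 ALKBH5-up rats, and Avil in 1 and 3. Runx1 and Runx3 had one in all 6.

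Endothelial, fibroblast, mural and blood markers had a peak in 16.0 ± 1.73 of 23 genes (SD, n = 3) in the ALKBH5-up and 13.0 ± 2.00 (SD, n = 3) in the NC-up rats (exact permutation p = 0.2, n = 3 per group). With folds above each list's median the difference was 0.333 members (exact p = 1). The collagen genes Col1a1 and Col1a2 had a peak in 1 NC-up and 3 ALKBH5-up rats, while Cdh5 and Myh11 had one in all 6. Macrophage and leukocyte markers had a peak in 14.7 ± 0.577 and 15.3 ± 0.577 of 23 genes (SD, n = 3; exact permutation p = 0.6), with Csf1r in 3 NC-up and 2 ALKBH5-up rats, S100a9 in 1 and 0, and Cd163 and Fcgr2b in all 6.

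Genes of the m6A machinery carried called peaks themselves, 18 of 28 in all 6 rats. These were 18 of the 23 members with any peak, beside 9541 of all 13112 genes with a peak (72.8%). Ythdc1, a nuclear m6A reader, and Zc3h13, a part of the m6A writer complex, had the highest fold percentiles, 99.1 and 98.8. The list had 20.3 ± 0.577 members with a peak (SD, n = 3) in the NC-up and 21 in each of the ALKBH5-up rats (exact permutation p = 0.4, n = 3 per group). In this list 3 members had a peak in more ALKBH5-up rats, Fxr2 (1 NC-up and 3 ALKBH5-up rats), Hnrnpa2b1 and Zcchc4 (0 and 1 each). Another 2, among them Mettl16 (3 and 2), had one in more NC-up rats. Nerve injury genes had a peak in 18 of 30 members in every NC-up rat and in 18, 21 and 18 in the ALKBH5-up rats (exact permutation p = 1), with Smad1 and Sox11 in all 6. Interferon and virus response genes had a peak in 17.7 ± 2.31 of 26 members in the NC-up and 17.0 ± 1.00 in the ALKBH5-up rats (SD, n = 3; exact permutation p = 0.8), and with folds above each list's median the difference turned to 1.33 more members in the ALKBH5-up rats (exact p = 0.3). Within that list 3 members, among them RT1-A2 (3 and 0 rats) and Irf3 (2 and 0), had a peak in more NC-up rats. Another 2, Stat2 and Bst2 (1 and 3 each), had one in more ALKBH5-up rats, and Isg15 and Zbp1 had one in all 6.

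**Figure D3:**
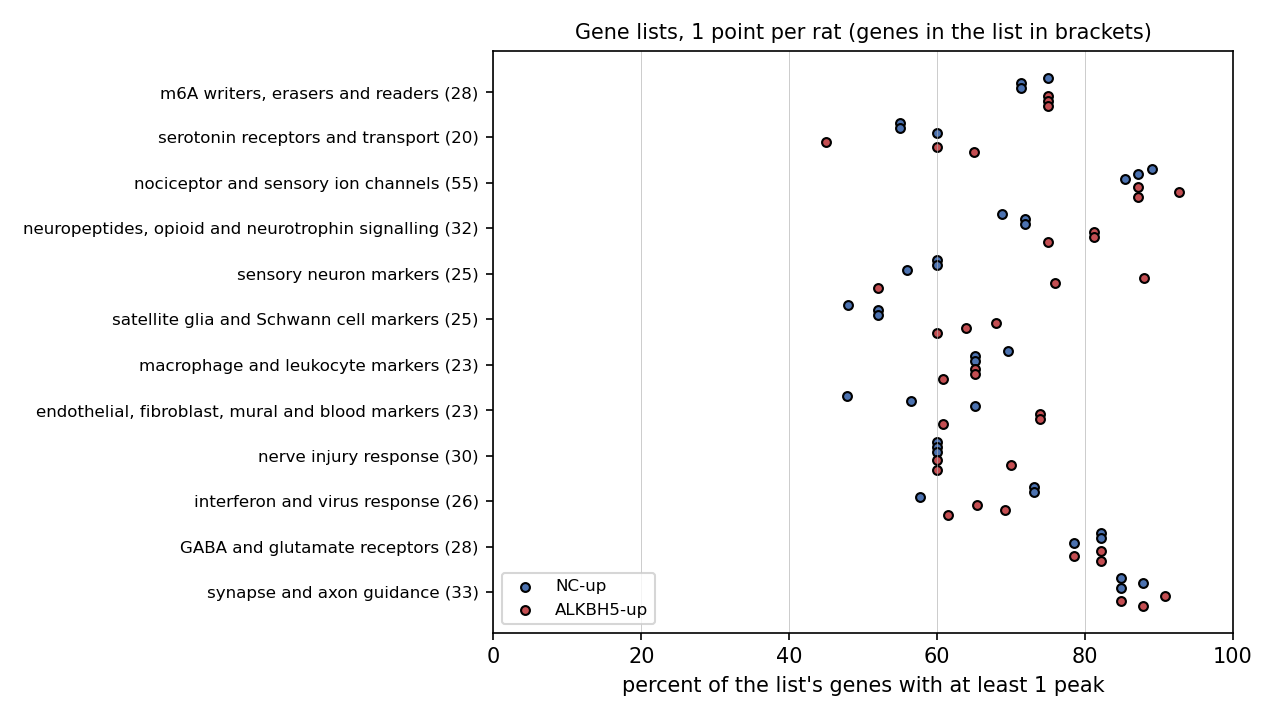
Share of the genes of each fixed list that had at least 1 peak, in percent, with 1 point per rat. With all peaks of the lists, the ALKBH5-up rats lie above the NC-up rats without overlap for the neuropeptide list (24 to 26 against 22 to 23 members) and the glial list (15 to 17 against 12 to 13 members).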

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

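The settings with a score of at least 50, without exon shifts, per gene with equal lists, and the overlap without each rat were chosen after seeing the data. The differences in peaks and in genes per rat kept their direction except with a fold of at least 11.03, which gave -8834 peaks and -3749 genes. That minimum is the NC-up median and lies above the upper fold quartile of every ALKBH5-up list (9.11, 8.99 and 10.6), so this turn follows from the lower fold scale and says nothing of peak number. Leaving out each rat gave 540 to 1933 peaks and 242 to 448 genes. The overlap difference (0.557 percentage points) stayed above 0 and came to 0.191 (exact permutation p = 0.9, without ALKBH5-up rat 1) to 1.15 (exact p = 0.1, without NC-up rat 2) without each rat. Regions called only in the NC-up rats (139) numbered 26 per gene, 82 with the 50% of each list that had the smallest p, 957 in at least 2 rats of a group, 81 at a score of at least 50, 31 per gene with equal lists, and 293 to 425 without each rat. Those called only in the ALKBH5-up rats (301) numbered 81, 151, 1468, 298, 65 and 514 to 906. Leaving out a rat, or asking for 2 of 3, loosens the rule. The cause of the other changes was not tested. Regions gained per region lost (2.17) came to 1.19 with equal lists, to 3.68 at a score of at least 50 and to 1.28 to 3.09 without each rat, and stayed above 1 in every alternative that could change it.

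Of the gene lists, the interferon list turned to 1.33 more members in the ALKBH5-up rats with folds above each list's median, and the synapse list to -2 there and -0.333 at a score of at least 50. The cause was not tested. Without ALKBH5-up rat 3, the neuropeptide list (lost regions) and the glial list (gained regions) had 5 members each. Adjusted p by Fisher's exact test was 0.00667 and 0.0498, while all lost regions rose from 139 to 293 and all gained regions from 301 to 906. Without each rat the counts were 3 to 5 and 3 to 5, and over all alternatives adjusted p was 0.00667 to 1 and 0.0498 to 1. Of the named genes, Htr5a turned to 33.3 and Dcc to -33.3 percentage points of rats at a score of at least 50, and Ramp1 to -33.3 with folds above each list's median.

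The rats share replicate numbers across the groups, and no clear pairing by number was seen. After removing group means, same-numbered rats had correlations of -0.00273, 0.0253 and 0.011 for the presence of regions. For log2 fold at regions called in all 6 rats they were -0.0464, 0.0369 and -0.00554. With 3 rats per group, removing the means makes each rat's correlations nearly cancel, so small values cannot exclude a pairing. By presence, NC-up rats 2 and 3 correlated best with their own number and NC-up rat 1 with ALKBH5-up rat 3 (0.012). With the replicate number as a block, the differences were 1152 peaks (exact sign-flip p = 0.5, smallest possible 0.25) and 325 genes (exact sign-flip p = 0.25), and 139 and 301 regions, which the block cannot change. The planned tests of read counts, normalized values, position and motif were not run. Counting every row and keeping chromosomes only removed no peak, so they tested nothing.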

Other observations

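Among the 81 genes called only in the ALKBH5-up rats were Cox4i1, Ndufa5, Ndufb5 and Ndufs3 of the respiratory chain, the glycolytic genes Pkm and Pfkp and the kinesin gene Kif5a, named after their values were seen. Of 273 pathways tested for the 41 of these genes with a pathway, the 3 genes of glycolysis had p = 0.00346 and the 4 of oxidative phosphorylation p = 0.0057 by one-sided Fisher's exact test, both with an adjusted p of 0.752. For the gained regions, oxidative phosphorylation had 8 genes (p = 0.0017 by the same exact test, adjusted p = 0.285). The lowest adjusted p of these pathway tests was 0.114, for genes called only in the NC-up rats, in pathways that held RT1-A2 and RT1-CE15, class I histocompatibility genes that can share reads. The glial list held 3 of the 81 genes, Fabp7, Pmp2 and Prx, 16.7% of its 18 members with a peak against 0.596% of the other genes (Fisher's exact test, adjusted p = 0.00416). Among genes called in exactly 3 rats, all 3 glial members were in these rats (p = 0.00299 by the same exact test, adjusted p = 0.0359), and so were all 3 cytosolic ribosomal protein genes called in exactly 3 rats (exact test, p = 0.00299), so this result was not particular to glia. The ribosomal test among these genes, both glial tests and the pathway tests were chosen after seeing the data.

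Of the tests that follow, equal lists and other splits were planned, with limits for the equal-list ratio set after it was seen. The shares of neighbouring exons, ribosomal protein genes and weak regions like that of Htr3a had their limits set before their results were seen, and the other tests were chosen after. More regions and genes were called only in the ALKBH5-up rats than only in the NC-up rats. The ALKBH5-up lists held more peaks on average, though ALKBH5-up rat 3 held fewer than NC-up rats 2 and 3, and with equal lists the ratio of regions was 1.19, so list length may account for most of the excess of regions, while the ratio of genes with equal lists was 2.1. Ribosomal protein genes, known for short and abundant mRNAs, were 3 of the 81 genes, an odds ratio of 8.91 (95% interval 1.75 to 28.4, Fisher's exact test p = 0.00576). Background reads from abundant mRNAs would give this, but it rests on 3 genes and abundance was not measured here, so it cannot decide. For the gained regions the ribosome pathway had 7 genes with 3.19 expected. Its one-sided Fisher's exact p of 0.0395 did not hold after adjustment over the pathways. A peak placed on a neighbouring exon was seen for 11.8% of the 440 group-specific regions, which stays open for those regions. With all rats, taking out these regions did not lower the excess: 119 and 269 regions were left, a ratio of 2.26 against 2.17. The limit for arguing against this cause had to hold with each rat left out as well, and it did not. Only peaks of the gene within 10 kb were counted, so exons further apart were not covered. Without each rat their removal left 96.9% to 114% of the ratio, which then ranged from 1.24 to 3.52. It was 1.24 without NC-up rat 1, 1.44 without NC-up rat 3 and 1.49 without ALKBH5-up rat 2. There the excess was small before their removal too (ratios of 1.28, 1.46 and 1.39), so these fits cannot decide its cause, which stays open. For chance, 2 of the 10 splits gave as many regions (440, highest other 455) and 1 of 10 as many genes (107, highest other 64), and 10 splits are too few for a share under 0.05.

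Fold enrichment was lower in the ALKBH5-up lists. A single unusual NC-up list is argued against, since without NC-up rat 1 the lowest NC-up median was still 1.28 times the highest ALKBH5-up median. More reads at a lower enrichment is a candidate explanation: at regions called in all 6 rats the ratio of mean score was 1.3, ALKBH5-up over NC-up. Less m6A after ALKBH5 injection, the biological explanation, stays open. The mean number of listed peaks was higher by 1152 in the ALKBH5-up lists, with overlapping groups. The peak numbering also counts peaks outside these lists. It ran to 73269, 76826 and 70688 in the ALKBH5-up rats, all above the NC-up rats (64607, 70530 and 68764). Less m6A would lower the number, but the number also depends on the depth, which was not analysed here, so it cannot decide. These explanations do not exclude each other.

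The Htr3a peak was called in 2 NC-up rats and no ALKBH5-up rat. Of 1126 regions called in NC-up rats 1 and 3 with a mean score under 30, as at Htr3a, 14.6% were absent from all 3 ALKBH5-up lists and 10.7% from NC-up rat 2 as well. Taken singly, 35.6% were absent from NC-up rat 2 and 38.9%, 32.1% and 45.6% from ALKBH5-up rats 1, 2 and 3. The regions compared may themselves include losses after ALKBH5, so these shares cannot separate a loss from a weak call. A call close to the detection limit may account for the Htr3a pattern, and a loss of m6A there stays open and untested.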
